A study of Homo sapiens with 6 samples.

How the data were processed

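Gene expression was measured by RNA sequencing in 6 libraries of Huh7, a line of human hepatocellular carcinoma cells, 3 treated with DMSO (the solvent control) and 3 with carfilzomib for 24 h. Carfilzomib is a proteasome inhibitor that binds the catalytic subunit PSMB5. The dose is not given in the sources used here. Groups and replicate numbers were taken from the sample titles and treatment labels. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, total RNA was isolated with a mirVana kit and libraries were made with a TruSeq Stranded mRNA kit.

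The authors deposited a single table of FPKM values (fragments per kilobase of gene, scaled to the library total), with 19021 rows named by gene symbol and 1 column per library. The submitters' processing notes name fastp, HISAT2, HTSeq, R 3.2.0 and DESeq2, without their role or order. The same notes name the genome build GRCm39, which is a mouse build, while 18164 of the 19021 row names are current human gene symbols and 224 more are older human symbols in the NCBI RefSeq gene table, and 2398 rows are named LOC followed by digits. Because the build behind the table is therefore unclear, no coordinates are given. Strand use and the handling of reads shared by similar genes are not given in the sources used here, so genes with near-identical copies, such as HSPA1A and HSPA1B, metallothioneins and histones, are uncertain.

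FPKM values hold whole reads divided by gene length and library total, and these were recovered from the ratios between libraries. In 19018 of the 19021 rows (99.98%) every value came out as whole reads in all 6 libraries, to a relative tolerance of 1e-13 in the ratios. The library totals were 39292337, 39601098 and 39651170 reads for DMSO replicates 1 to 3, and 39205256, 38386581 and 39098662 reads for carfilzomib replicates 1 to 3. The listed genes hold 99.6% of them in each library. In simulated data of 3995 genes the procedure found all 6 library totals exactly, called all 3975 untouched rows whole, gave the simulated reads in 3937 of them, and called none (0) of 20 altered rows whole. The 3 rows that were not whole are GADD45A, GADD45B and GADD45G.

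Because FPKM values are not counts, the main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. Rows with a mean of at least 1 FPKM over the 6 libraries were tested, which left 11153 genes. Differences are on the log2(FPKM + 1) scale, which understates the change of low genes. A second rule asked for a difference of at least 1 (2-fold) as well. Adjusted p-values of single genes are from this limma fit throughout. In simulated data with the spread of these 11153 genes and 200 genes changed, the fit called 50% of genes changed by 0.25, 82% of those changed by 0.5, and 100% of those changed by 1 or 2 on the log2 scale, and it called 4 unchanged genes. In the real data the fit called 9096 genes, and with more changed genes the adjustment is less strict. These simulated shares and false calls therefore do not measure the sensitivity or the false calls of the real comparison.

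The 37 gene lists, the test and the rule for named genes were fixed before the data were examined, and the 36 with at least 3 tested members were tested as sets with camera (limma, preset inter-gene correlation 0.01, two-sided), with Benjamini-Hochberg adjustment over the lists. Adjusted p-values of lists are from camera unless another test is named. The rule named GADD45A, GADD45B, GADD45G and PSMB5, then the 6 largest rises and 6 largest falls among genes with an adjusted p under 0.05 whose groups do not overlap (leaving out rows with no gene symbol, Y-linked genes and XIST), then from each list with a call the 2 members with the largest change in each direction among those with an adjusted p under 0.05, and the reference genes HSPA1A, HSPA5, DDIT3, ATF3, HMOX1, SQSTM1, CDKN1A, MDM2, MYC, CCND1, MKI67, ALB and AFP. For lists without a call, members were named in the same way, an extension of the rule made after the values were seen. Some genes that the rule names are not reported here. GADD45A was also given an exact two-sided permutation test over the 20 label assignments. Values are means ± SD over the 3 libraries of a group.

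The alternatives tried were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, median-of-ratios scaling, rescaling to TPM, quantile normalization, the replicate number as a block, limma without the trend and with robust fitting, each library left out in turn, and for the lists camera with an estimated correlation, camera on ranks and fry. After the data were seen, limma-voom on the recovered reads and a fit without the 3 GADD45 rows were added. Libraries of a group differed by more than counting noise (chi-square per degree of freedom 3.70 to 7.18 over pairs), so all were kept as separate samples. Each library was also compared with the other 2 of its group, over all tested genes and per list, a step added after the data were seen, as was the share of 80% of members used to report it. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Counting intervals are exact at the 95% level and cover counting error only.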

Results

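The transcriptome of Huh7 cells was compared after 24 h with DMSO or carfilzomib, with 3 libraries in each group. The library totals behind the FPKM values were 38386581 to 39651170 reads. The comparison asks how the drug changes gene expression, and the series title names GADD45A, a growth-arrest and DNA-damage-inducible gene, as raised by the drug. Across genes, log2(FPKM + 1) correlated with a Pearson r of 0.998 between every pair of libraries of a group (6 pairs) and of 0.959 to 0.961 between groups, where genes are not independent replicates. The first principal component held 96.0% of the variance and separated the groups. DMSO replicate 1 lay apart from the other DMSO libraries on the second, which held 1.22% of the variance (8.43 against -3.69 and -4.72), and its values are given beside the gene lists in which at least 80% of members were higher in it than in both others. Of all 11153 tested genes, 3465 were higher in it than in both others and 4667 were lower in it than in both. Other libraries are also given beside a list where at least 80% of its members lay on the same side of both others.

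Most expressed genes differed between the groups. Heat shock genes were among those that rose most. The 6 largest rises were in HSPA6 and HSPA1A, both inducible HSP70 chaperones, HSPA1B, a near-identical copy of HSPA1A, CRYAB, a small heat shock protein, FOSL1, a subunit of the AP-1 transcription factor, and CLDN4, a tight-junction claudin. HSPA1A went from 6.26 ± 0.242 to 1122 ± 32.6 FPKM (SD, n = 3), a log2 difference of 7.27 (SE 0.0349, adjusted p = 1.34e-14 by limma). HSPA6 had 2, 2 and 1 reads in the DMSO libraries and 15229, 16131 and 17317 with carfilzomib, a ratio of 9890 with a 95% exact counting interval of 4238 to 30461. The log2 differences were 6.30 for HSPA1B, 5.42 for CRYAB, 4.93 for FOSL1 and 4.32 for CLDN4. Among the 6 largest falls were CXCL10, a chemokine (15.9 ± 0.866 to 0.430 ± 0.185 FPKM), H2BC17, a histone H2B gene, GATM, an enzyme of creatine synthesis (80.0 ± 0.577 to 8.81 ± 0.395), HAMP, which encodes the iron hormone hepcidin (59.1 ± 3.02 to 7.23 ± 1.43), and TMEM86B (22.7 ± 1.42 to 2.37 ± 0.543). H2BC17 had 7, 4 and 3 reads with carfilzomib against 716 over the DMSO libraries, a ratio of 0.0199 (95% exact counting interval 0.0108 to 0.0335).

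Of 11153 genes tested, limma called 9096 (81.6%), 4089 higher and 5007 lower with carfilzomib. The excess of lower calls depends on the scaling, with 4572 higher and 4507 lower after median-of-ratios scaling and 4537 higher and 4576 lower after quantile normalization. Without DMSO replicate 1, 3994 were higher and 4982 lower. At least 2-fold, 589 were higher and 874 lower (13.1% of those tested). These 2-fold counts depend on the pseudocount and the fit, with 269 genes at least 2-fold higher and 334 genes at least 2-fold lower at a pseudocount of 5, 796 and 1326 at 0.1, and 825 and 1377 with limma-voom on recovered reads. The groups did not overlap in 9239 genes (82.8%), where chance gives 10%, and the median spread within a group was 0.0615 on the log2 scale.

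**Figure D1:**
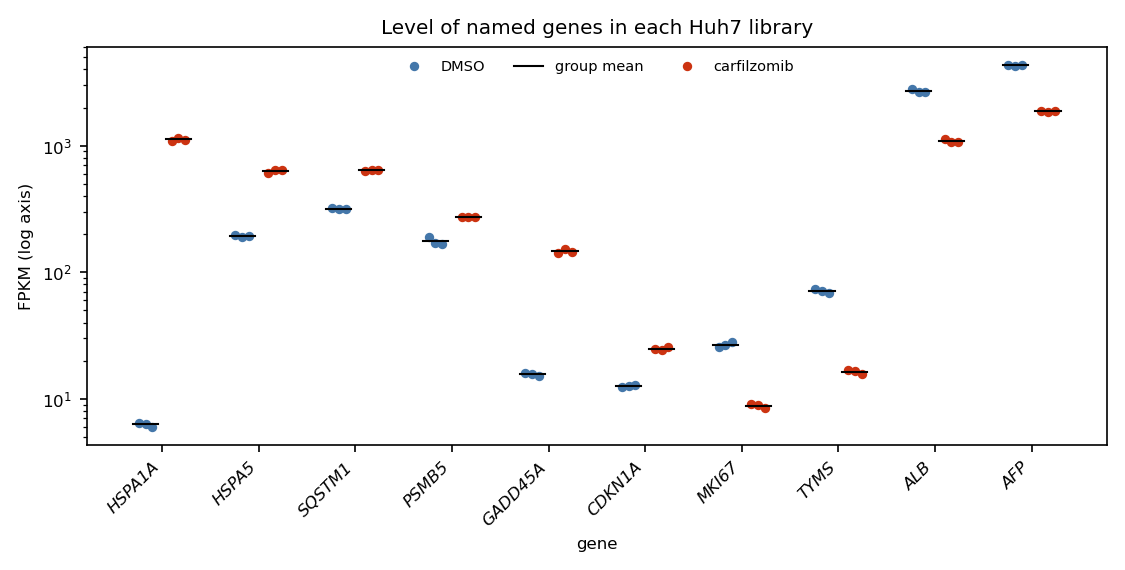
FPKM (log axis) of 10 named genes in each library, with points for the 3 DMSO and 3 carfilzomib libraries and bars for group means. HSPA1A goes from a mean of 6.26 to 1122 FPKM and ALB from 2699.8 to 1089.9. The DMSO values of GADD45A are not whole reads.

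Genes of the proteasome, the protease complex that carfilzomib inhibits, rose together. All 14 core-particle genes were higher, with PSMB7 at 219 ± 10.9 and 445 ± 8.59 FPKM, PSMB2 at 66.1 ± 1.21 and 126 ± 2.72, and the drug's target PSMB5 at 176 ± 11.7 and 273 ± 1.79 FPKM (log2 difference 0.63, SE 0.0429, adjusted p = 3.49e-07 by limma). All 19 genes of the regulatory particle were higher too, led by the ATPase PSMC4 (3.11 times) and the scaffold PSMD2 (2.57 times). In DMSO replicate 1, 13 of the 14 core genes were higher than in both other DMSO libraries (median log2 difference from them 0.10). In carfilzomib replicate 2, 12 of the 14 were higher than in both other carfilzomib libraries (median log2 difference from them 0.04). Both lists were higher by camera (adjusted p = 6.12e-06 for the core and 1.67e-08 for the regulatory particle), and with an estimated correlation the adjusted p was 0.3003 and 0.189. Among 17 activators, assembly factors and immunoproteasome genes, 8 rose, 4 fell and 5 did not pass, and the list had no call (adjusted p = 0.273). ZFAND2A, an arsenite-inducible proteasome-associated protein, rose 13.1 times and the assembly chaperone POMP 2.05 times, while the activator subunits PSME1 (76.2 to 52.2 FPKM) and PSME2 (101 to 69.7 FPKM) fell. Of 24 ubiquitin and p97 pathway genes, 13 rose, 7 fell and 4 did not pass (adjusted p = 0.0382, and adjusted p = 0.193 with an estimated correlation). UFD1, a p97 cofactor, rose 2.63 times, and HDAC6 (19.2 to 9.89 FPKM) and the protease DDI2 (12.1 to 7.06 FPKM) fell. This list lost its call with a mean of at least 5 FPKM (adjusted p = 0.0869) and with quantile normalization (adjusted p = 0.128), over a range of 0.0193 to 0.193 in 20 alternatives with camera.

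Chaperone genes of the cytosol and of the endoplasmic reticulum rose. Of 31 cytosolic heat shock genes, 29 rose, 26 of them at least 2-fold, and the list's share of all reads went from 0.553 ± 0.00571% to 2.26 ± 0.0548% (SD, n = 3). The exceptions were HSF2, a heat shock factor (10.9 to 9.44 FPKM), and STUB1, a chaperone-linked ubiquitin ligase (33.3 to 28.2 FPKM), which fell, although the HSF2 call was lost with median-of-ratios scaling (adjusted p = 0.0735 by limma) and quantile normalization (adjusted p = 0.0909), over a range of 0.00443 to 0.0909 in 18 alternatives. In carfilzomib replicate 1, 25 of the 31 heat shock genes were lower than in both other carfilzomib libraries (median log2 difference from them -0.06). Of 25 genes of endoplasmic reticulum chaperones and degradation, 20 rose, 3 fell and 2 did not pass. HSPA5, the HSP70 of the endoplasmic reticulum, went from 193 ± 3.00 to 632 ± 18.7 FPKM and SDF2L1 from 21.8 ± 3.69 to 43.8 ± 2.91, while XBP1, a transcription factor of the unfolded protein response, fell from 412 ± 2.78 to 248 ± 1.18 and PDIA4 from 120 ± 3.47 to 94.6 ± 1.40. Autophagy and lysosome genes rose in 23 of 27 cases and fell in 3. GABARAPL1, an ATG8-family gene, went from 25.2 ± 0.301 to 172 ± 5.06 FPKM, ATG16L1 rose 2.11 times, and SQSTM1, the ubiquitin-binding autophagy receptor p62, went from 318 ± 4.64 to 640 ± 4.58, whereas NBR1, another receptor, and GABARAP fell (16.2 to 11.3 and 162 to 134 FPKM). The lists were higher by camera, with adjusted p = 4.69e-13 for cytosolic heat shock, 1.06e-04 for the endoplasmic reticulum and 3.39e-05 for autophagy, and each had an adjusted p of 0.189 with an estimated correlation.

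Stress-response targets moved in mixed directions. Of 31 targets of NRF2, the oxidative-stress transcription factor, 20 rose and 9 fell (adjusted p = 0.0118, and adjusted p = 0.339 with an estimated correlation). MAFF rose 4.84 times, the thioredoxin reductase TXNRD1 2.92 times, and HMOX1, heme oxygenase, 1.82 times (41.9 ± 1.08 to 76.2 ± 3.25 FPKM), while the reductase AKR1B10 fell from 10.6 to 3.06 FPKM and the transporter ABCC3 from 11.4 to 5.66. Among 26 targets of ATF4 and CHOP, transcription factors of the integrated stress response, 9 rose and 16 fell, and the list had no call (adjusted p = 0.288). PPP1R15A, a phosphatase subunit that reverses eIF2 phosphorylation, rose 3.03 times and ATF3 2.24 times. DDIT3, which encodes CHOP, fell from 43.9 ± 5.39 to 32.8 ± 1.55 FPKM, CHAC1 from 10.4 ± 0.660 to 2.59 ± 0.271, and PSPH, of serine synthesis, from 73.5 ± 0.327 to 23.9 ± 1.23. Cytosolic aminoacyl-tRNA synthetases had 6 higher and 12 lower of 20 (adjusted p = 0.436), with HARS1 and WARS1 higher (2.35 and 1.67 times) and AARS1 (177 to 113 FPKM) and FARSB (10.7 to 6.63) lower. Of 6 metallothioneins, 5 rose and 1 fell without a call for the list (adjusted p = 0.0731), which passed without a filter (adjusted p = 0.0421) and without carfilzomib replicate 2 (adjusted p = 0.0458), over a range of 0.0421 to 0.339 in 20 alternatives with camera. In DMSO replicate 3, 5 of the 6 metallothioneins were lower than in both other DMSO libraries (median log2 difference from them -0.16). MT1M rose 4.29 times and MT2A 2.01 times, and MT1F, the member that fell, lost its call in 11 of 18 alternatives. Its log2 difference was -0.27, and -0.15 without DMSO replicate 1 (adjusted p = 0.142 by limma, over a range of 0.00204 to 0.142), and the call was also lost without DMSO replicate 2 (log2 difference -0.27) and without carfilzomib replicate 2 (-0.24) or 3 (-0.22).

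GADD45A, the gene of the series title, was listed at 15.7 ± 0.468 FPKM with DMSO and 146 ± 5.70 with carfilzomib (SD, n = 3), a ratio of 9.33 and a log2 difference of 3.14 (SE 0.0375, adjusted p = 7.57e-12 by limma). Its 3 carfilzomib values lay above its 3 DMSO values, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. GADD45B was listed at 61.2 ± 1.84 and 117 ± 5.37 FPKM and GADD45G at 5.71 ± 0.0646 and 20.01 ± 1.82, log2 differences of 0.93 and 1.64. All 3 genes were higher in DMSO replicate 1 than in both other DMSO libraries (median log2 difference from them 0.05). All 3 were also lower in carfilzomib replicate 1 than in both other carfilzomib libraries (median log2 difference from them -0.10). The family list was called higher (adjusted p = 0.00841, and adjusted p = 0.225 with an estimated correlation), which is not independent evidence for GADD45A, since the series names it. In the table used here, the 9 carfilzomib values of these 3 genes are whole reads, for GADD45A 7505, 7925 and 7660, while the 9 DMSO values are not whole reads, unlike every value in the other 19018 rows. How those DMSO values were made is not known, so the GADD45 differences carry this limit.

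**Figure D2:**
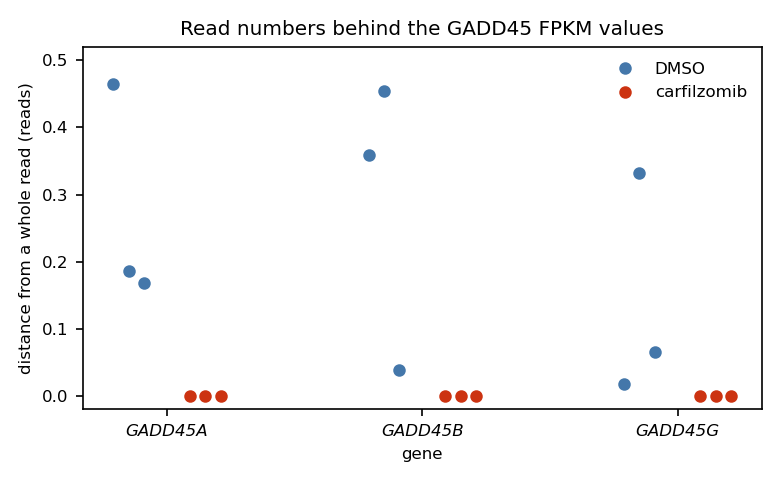
Distance from the nearest whole read of the read numbers behind the FPKM values of the 3 GADD45 genes, in each library, at the gene length that makes the carfilzomib values whole. The 9 carfilzomib values lie at 0, and the 9 DMSO values lie at least 0.0175 reads away.

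Targets of p53, the tumour suppressor that is mutated in Huh7 cells, moved both ways. Of 19 tested, 6 rose, 9 fell and 4 did not pass (adjusted p = 0.999), with a mean log2 difference of 0.06 but a median of -0.11 and a camera direction of lower, while fry, which tests a list against no change, called it higher (adjusted p = 0.00481). CDKN1A, the cyclin-dependent kinase inhibitor p21, went from 12.6 ± 0.213 to 24.8 ± 0.747 FPKM, AEN rose 2.94 times and the kinase PLK3 3.18 times, while CCNG1 fell from 49.8 to 27.6 FPKM and BBC3, which encodes the cell-death protein PUMA, from 9.30 to 5.78. MDM2, the ubiquitin ligase of p53, had 8.41 ± 0.175 and 8.62 ± 0.216 FPKM (adjusted p = 0.503 by limma), although it passed with median-of-ratios scaling (adjusted p = 0.0459) and quantile normalization (adjusted p = 0.00993), over a range of 0.00993 to 0.787 in 18 alternatives. In the BCL2 family of apoptosis regulators, 6 of 13 rose and 5 fell (adjusted p = 0.506). The survival genes MCL1 and BCL2L2 rose 1.73 and 1.80 times, and the death gene BCL2L11 fell from 7.65 to 4.96 FPKM, as did BBC3.

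Genes of cell division fell. All 27 genes of the G2 and M phases were lower, 19 of them at least 2-fold, with CCNA2, cyclin A2, going from 47.3 ± 0.913 to 11.8 ± 1.11 FPKM, TOP2A, a topoisomerase, from 79.0 ± 1.54 to 22.1 ± 0.776, and MKI67, the proliferation marker Ki-67, from 26.8 ± 1.36 to 8.84 ± 0.290. Of 32 genes of the G1/S transition and DNA replication, 29 fell, 2 rose and 1 did not pass. TYMS, the thymidylate synthase, fell from 71.1 ± 2.23 to 16.4 ± 0.706 FPKM, and CCND1, cyclin D1, from 65.0 ± 1.58 to 57.0 ± 0.257. GINS3 and CDC25A rose by 0.20 and 0.17 on the log2 scale. The GINS3 call was lost without DMSO replicate 2 (log2 difference 0.12) and without carfilzomib replicate 2 (0.18) or 3 (0.19), as well as without a filter, and the CDC25A call without DMSO replicate 1 (0.13) and without carfilzomib replicate 2 (0.12). Homologous recombination and Fanconi genes fell in 16 of 18 cases and none (0) rose, with EXO1 going from 11.6 to 3.61 FPKM and RAD51AP1 from 22.3 to 8.17. Of 8 histone genes, 7 fell, including H1-2 (172 ± 7.04 to 40.5 ± 1.78 FPKM) and H2AC6 (108 ± 2.50 to 30.5 ± 3.06). Most such histone transcripts lack a poly(A) tail, which the library kit selects for. H2BC21, the member that rose (6.72 to 7.94 FPKM), had a log2 difference of 0.22 and lost its call in 6 of 18 alternatives, including those without a filter, without DMSO replicate 1 (0.14) or 3 (0.22) and without carfilzomib replicate 1 (0.17) or 3 (0.21). The adjusted p by camera was 4.09e-09 for G2 and M, 2.35e-07 for G1/S, 2.36e-04 for repair and 0.00991 for histones, and with an estimated correlation the adjusted p was 0.191, 0.193, 0.189 and 0.193.

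Genes that mark hepatocytes fell. All 30 tested genes of secreted liver plasma proteins were lower, 23 at least 2-fold, and the list's share of all reads went from 4.52 ± 0.0165% to 2.04 ± 0.0577%. ALB, albumin, went from 2699.8 ± 87.4 to 1089.9 ± 26.4 FPKM and AFP, alpha-fetoprotein, from 4306 ± 27.3 to 1870.5 ± 13.3. APOC3, an apolipoprotein, fell from 52.4 ± 3.19 to 9.68 ± 2.02 and HP, haptoglobin, which has a close copy in HPR, from 59.0 ± 6.73 to 11.7 ± 1.75. Of 19 hepatocyte transcription factors and metabolic enzymes, 18 fell, including the factor ONECUT1 (9.46 ± 0.481 to 1.01 ± 0.132), and HPD, an enzyme of tyrosine breakdown, rose from 1.45 ± 0.138 to 9.90 ± 0.567. The adjusted p by camera was 7.69e-10 for plasma proteins and 3.39e-05 for factors and enzymes, and 0.189 in both cases as an adjusted p with an estimated correlation.

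Lipid synthesis and mitochondrial genes fell as well. Of 26 genes of cholesterol synthesis and SREBP2 targets, 22 fell and 3 rose (adjusted p = 6.20e-04, and adjusted p = 0.319 with an estimated correlation). EBP, a sterol isomerase, fell from 226 ± 7.75 to 73.8 ± 1.35 FPKM and the sterol reductase TM7SF2 from 14.9 ± 1.32 to 1.84 ± 0.790, while HMGCS1 rose 1.79 times. Fatty acid and triglyceride synthesis genes fell in 15 of 17 cases (adjusted p = 7.99e-04, and adjusted p = 0.193 with an estimated correlation), with the triglyceride-forming enzymes DGAT2 at 24.4 and 5.37 FPKM and DGAT1 at 16.1 and 4.25, and LPIN1 and ELOVL5 higher (1.87 and 1.67 times). All 13 mRNAs encoded by mitochondrial DNA were lower (adjusted p = 9.54e-04, and adjusted p = 0.216 with an estimated correlation), from 5.91 ± 0.0647% to 4.40 ± 0.0464% of all reads. COX2, a cytochrome oxidase subunit, had 10025 ± 152 and 6321 ± 103 FPKM and ATP8 2375 ± 687 and 1236 ± 73.8. ATP8 was highest in DMSO replicate 1 (3168 FPKM against 1985 and 1971), while 6 of the 13 mRNAs were higher and 7 lower in that library than in both other DMSO libraries. With quantile normalization this list lost its call (adjusted p = 0.372, over a range of 4.75e-05 to 0.372 in 20 alternatives with camera). Of 36 nuclear genes of oxidative phosphorylation, 27 fell, 2 rose and 7 did not pass (adjusted p = 9.25e-04, and adjusted p = 0.415 with an estimated correlation). NDUFV1 of complex I went from 231 to 106 FPKM and CYC1, cytochrome c1, from 55.3 to 31.6, while NDUFA4 rose 1.20 times and SDHD 1.10 times, the SDHD call being lost with quantile normalization (adjusted p = 0.0681 by limma, over a range of 0.00169 to 0.0681) and without DMSO replicate 3 (log2 difference 0.09) or carfilzomib replicate 2 (0.13) or 3 (0.13), from 0.14 with all libraries. In DMSO replicate 1, 29 of these 36 nuclear genes were higher than in both other DMSO libraries (median log2 difference from them 0.09, NDUFA4 at 124 FPKM against 106 and 104), and without it 4 rose and 26 fell.

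**Figure D3:**
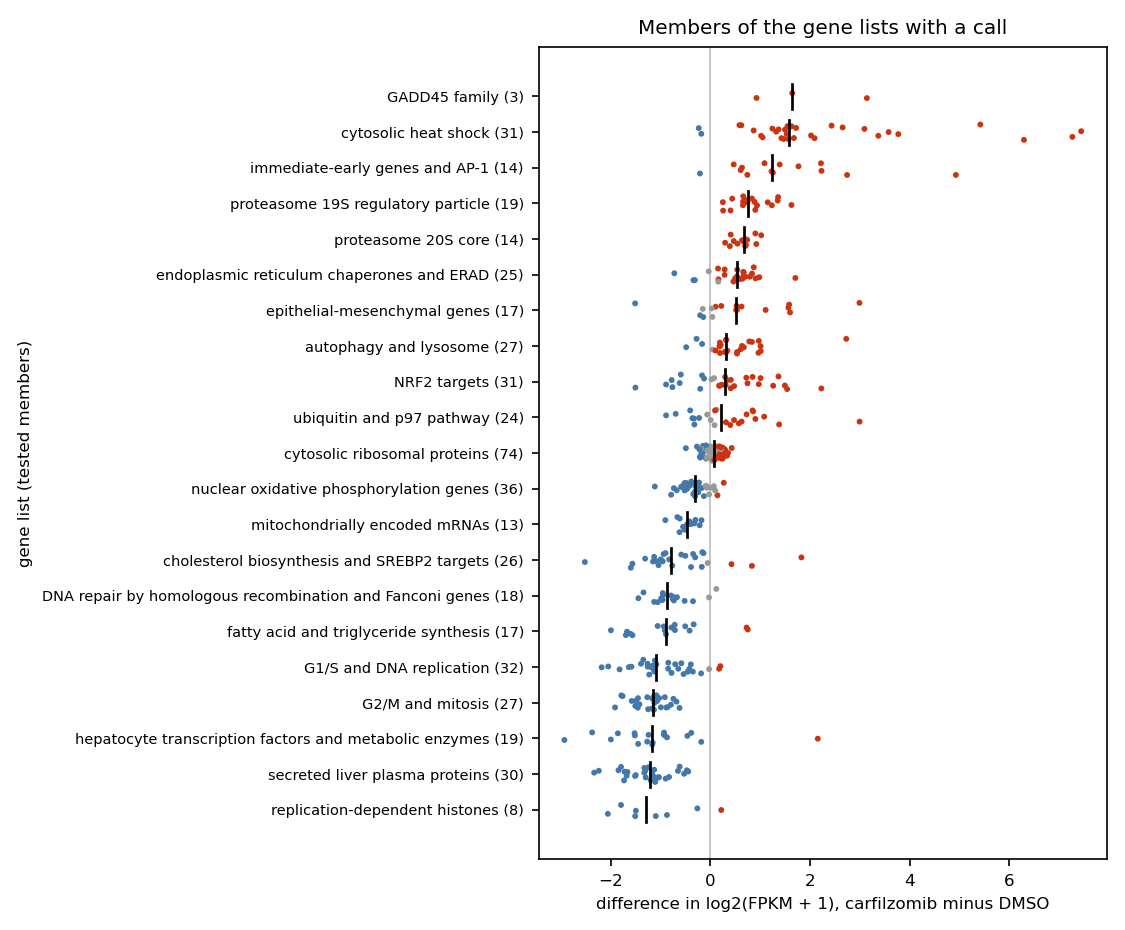
Difference in log2(FPKM + 1), carfilzomib minus DMSO, of each tested member of the 21 gene lists with a call (points, red higher, blue lower, grey not called), with the list median as a bar. Cytosolic heat shock has a median of 1.57 and secreted liver plasma proteins of -1.22. The direction of the cytosolic ribosomal protein list flips with quantile normalization, and the GADD45 family rests on DMSO values that are not whole reads.

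Immediate-early genes and most genes of an epithelial-mesenchymal list rose. Of 14 immediate-early and AP-1 genes, 13 rose, 9 at least 2-fold, and JUND fell from 107 to 92.7 FPKM (adjusted p = 6.12e-06, and adjusted p = 0.189 with an estimated correlation). FOSL1 went from 0.868 ± 0.238 to 55.7 ± 1.39 FPKM, DUSP1, a phosphatase of MAP kinases, from 53.2 ± 1.80 to 362 ± 12.6, and the transcription factor MYC from 26.0 ± 0.883 to 40.2 ± 1.76. Of 17 epithelial-mesenchymal genes, 11 rose and 3 fell (adjusted p = 0.00841, and adjusted p = 0.189 with an estimated correlation). This list holds both epithelial and mesenchymal genes, so its direction alone does not mark a shift to either state. VIM, vimentin, went from 140 ± 1.46 to 428 ± 12.8 FPKM, while CDH1, E-cadherin, fell from 42.5 ± 1.08 to 14.2 ± 0.382 and FN1, fibronectin, from 945 to 819. In NF-kB targets, 10 of 17 rose and 5 fell (adjusted p = 0.0917), with the cytokines CXCL8 and IL6 at 2.58 and 3.22 times the DMSO level and CXCL10 and TNFAIP2 (48.0 to 32.4 FPKM) lower. Among 13 interferon-stimulated genes 7 rose and 1 fell (adjusted p = 0.0760), MX1 by 1.37 and OAS1 by 0.84 on the log2 scale. Tubulins rose in 7 of 11 cases and fell in 3 (adjusted p = 0.0885), TUBB3 4.09 and TUBA4A 4.23 times higher, and TUBB (393 to 213 FPKM) and TUBG1 (41.1 to 20.1) lower. In DMSO replicate 1, 9 of the 11 tubulins were higher than in both other DMSO libraries (median log2 difference from them 0.03).

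Ribosomal and glycolytic genes moved little or both ways. Of 74 cytosolic ribosomal protein genes, 33 rose, 13 fell and 28 did not pass (adjusted p = 0.0435, and adjusted p = 0.727 with an estimated correlation), with a median log2 difference of 0.08, from RPL39 at 0.43 and RPS19 at 0.35 to RPS2 at -0.49 and RPS10 at -0.27. In DMSO replicate 1, 60 of the 74 were higher than in both other DMSO libraries (median log2 difference from them 0.09, RPL39 at 449 FPKM against 371 and 357), and without it 43 rose and 12 fell. In DMSO replicate 3, 56 were lower than in both others, and in carfilzomib replicate 2, 65 were higher than in both other carfilzomib libraries. The direction flipped with quantile normalization (adjusted p = 0.516). The call was also lost with a mean of at least 5 FPKM (adjusted p = 0.128), with camera on ranks (0.0537), with fry (0.191), without DMSO replicate 2 (0.0891) or 3 (0.126) and without carfilzomib replicate 2 (0.0954), over a range of 6.35e-04 to 0.727 in 20 alternatives with camera. The RPS10 call was lost in 10 of 18 alternatives, including those without DMSO replicate 1 (log2 difference -0.24) or 3 (-0.27) and without carfilzomib replicate 2 (-0.26) or 3 (-0.15). Ribosome biogenesis genes had 11 higher and 6 lower of 25 (adjusted p = 0.288), with RRP12 2.85 and PES1 1.41 times higher, and UBTF (15.5 to 8.50 FPKM) and POLR1B (7.85 to 4.79 FPKM) lower. Glycolysis and hypoxia genes had 11 higher and 8 lower of 20 (adjusted p = 0.341), with ADM, adrenomedullin, 5.03 times and HK1, hexokinase 1, 12.8 times higher from a DMSO level of 0.223 ± 0.0442 FPKM, and PFKL (26.6 to 12.02 FPKM) and the lactate transporter SLC16A3 (30.0 to 17.9 FPKM) lower.

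Lists of markers of other cell types and RNA quality had no call by camera, while fry called cholangiocyte (adjusted p = 1.42e-05) and immune markers (0.00441) higher and fibroblast and stellate markers (1.66e-04) lower, and RNA quality had no call by fry either (0.488). Cholangiocyte markers had 2 higher and 3 lower of 5 (adjusted p = 0.922, median log2 difference -0.25 but mean 0.16 and a camera direction of higher), SPP1 3.77 and KRT19 1.93 times higher and EPCAM (44.1 to 35.1 FPKM) lower. Immune markers had 2 higher (CD3D at 0.451 and 1.73 FPKM, CD68 at 33.2 and 46.9) and 1 lower (LYZ at 319 and 172) of 3 (adjusted p = 0.474). In carfilzomib replicate 1, all 3 immune markers were higher than in both other carfilzomib libraries (median log2 difference from them 0.15). Fibroblast and stellate markers had COL1A2 (5.93 to 3.41 FPKM) and LUM (12.3 to 10.8) lower and 1 not passed of 3 (adjusted p = 0.353). The single tested endothelial marker, PECAM1, was lower (3.94 to 2.58 FPKM), and this list was too short for a test. Among 10 nuclear-retained and snoRNA host RNAs, read as a sign of RNA quality, 6 rose and 2 fell (adjusted p = 0.372), MALAT1 1.77 and NEAT1 1.58 times higher and SNHG8 (47.0 to 18.3 FPKM) and SNHG1 (97.8 to 70.7) lower. Members moved both ways, which a test of a shared direction can miss. For change in either direction, fry gave an unadjusted p of 6.59e-07. The missing calls therefore do not show that RNA quality was alike in both groups. Of these 10 RNAs, 9 were higher in DMSO replicate 1 than in both other DMSO libraries (median log2 difference from them 0.20), with MALAT1 at 21.5 FPKM against 14.98 and 16.4 and SNHG8 at 53.6 against 43.0 and 44.4, and without it 6 rose and 2 fell.

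Of the 36 lists tested, 11 were higher and 10 lower by camera, and none (0) was called with an estimated correlation, where the lowest adjusted p was 0.189 and 9 lists had an unadjusted p under 0.05, while fry, which does not compare a list with other genes, called 21 higher and 13 lower, leaving out the ribosomal protein and RNA quality lists. Adjusted over the list alone, the counts of members that rose or fell were the same in 35 of the 37 lists, and they changed by 1 gene for the endoplasmic reticulum list (21 rose) and the ribosomal protein list (12 fell).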

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

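Of the tests in this part, those of gene length, library total and decimals for the GADD45 values, of depth and of thin background for the silent genes, of other splits for the counts of genes, and of median-of-ratios scaling for the plasma protein genes were chosen after the result was seen.

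A signal appeared among genes left out of the tests for low expression. Of 7868 such rows, 37 had no read in any DMSO library and at least 10 reads in each carfilzomib library, against 2 with the reverse. Among the 37, chosen here after their values were seen, were PEAR1 (61.3 ± 15.4 reads per carfilzomib library, SD, n = 3), CSRP3, a muscle LIM protein (55.3 ± 13.4), KRT34, a hair keratin (52.3 ± 12.01), and CD53, a leukocyte tetraspanin (51.7 ± 12.1). The 2 reverse rows were the histone gene H4C15 (28.7 ± 13.4 reads per DMSO library) and PERCC1 (18 ± 4.58).

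Deeper sequencing with carfilzomib, judged by the library totals behind the FPKM values, is argued against as their source. The highest carfilzomib total (39205256 reads) lay below the lowest DMSO total (39292337 reads). A thin background at 1 rate per kb over the 387 genes without a DMSO read was tested in 3 ways. Such a rate gives 80.4 genes with at least 10 reads in each carfilzomib library, where 42 were seen (tested genes included), which does not separate the explanations because those genes set the rate, and it gives 27.1 genes with at most 3 reads, where 9 were seen, but the table holds few rows of under 7 reads in all (0.2997% of rows). The last test found 55 genes above 3 times that rate, where counting noise gives 0.234. That figure takes no account of the missing rows of under 7 reads. Short genes that are listed can exceed the rate for that reason alone, so this test does not decide either. A background, uniform or differing from gene to gene, stays open. Reads from immune cells cannot be told apart from expression by these cells: the 4 immune markers with few DMSO reads had a median of 12 reads per carfilzomib library, but they went both ways, with PTPRC at 0.333 and 4, CSF1R at 0 and 4, CD3D at 14.7 and 55.3 and CD14 at 85 and 20 mean reads with DMSO and carfilzomib, so an effect of the drug remains a hypothesis.

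The read numbers behind the GADD45 rows are a pattern of the table, and no biological explanation was tested. Another gene length is argued against, since 0 of the 3 genes has a length up to 20000 that makes its DMSO values whole reads, and so is another library total, since 0 of 9 ratios between the genes within DMSO libraries were ratios of whole numbers, against 9 of 9 with carfilzomib. Reads split in equal shares between similar genes are argued against too, as 0 of the 9 values became whole when multiplied by any whole number up to 100. Reads split in other proportions need not become whole in that way, so the test leaves such a split open. At the lengths and totals that make the carfilzomib values whole, all 9 DMSO read numbers end within 9 decimals (GADD45A replicate 1 at 853.54 reads), which 3.5% of values do at neighbouring lengths, so these values may have been computed from read numbers that already held decimals. What produced such numbers stays open, and with it the size of the GADD45 changes.

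The fall of plasma protein genes (median log2 difference -1.22 over 30 genes) was weighed against 2 technical explanations. Reads taken up by rising genes shift all other genes alike, and they are argued against as the whole cause by median-of-ratios scaling, which moved the median of all genes by 0.07 and left the list at -1.15 (SD over members 0.485), with 30 of 30 genes called lower by limma. An earlier test, which set the list's fall against the change of -0.54 in the share of all genes whose share fell, gave 2.27 times where 3 times had been set as the bound, and is void because those genes were picked by their change. Of 10000 random lists matched on gene length and DMSO level, the lowest median was -0.59, which argues against a broad trend with length or level. The match used broad groups of length and level. A trend within the group of the highest genes, such as ALB and AFP, therefore stays open. An effect of carfilzomib on hepatocyte gene expression stays a hypothesis, and a change in total RNA per cell, which scaling to the median gene leaves open, was not measured.

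The 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 9096 genes and 1463 at least 2-fold, and the highest of the others called 0 of either by limma, with 10 to 22 genes at an unadjusted p under 0.05. In each case 1 of the 10 splits, the real one, gave as many. Every other split mixes both treatments within a group, so the treatment difference adds to the spread and calls are bound to be few. Their 0 calls are therefore no baseline for chance. For the gene lists, camera called 21 in the real split and up to 21 in the others, so 2 of 10 splits gave as many, and each other split still sets 2 libraries of a treatment against 1, so that it carries part of the treatment difference.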

How the results depend on the processing

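The fits with limma-voom on recovered reads and without the 3 GADD45 rows were chosen after the data were seen. Counts of genes called stayed within 1.5 times the reported counts under every alternative, except that 3246 genes were lower with a mean of at least 5 FPKM, which tests fewer genes (7375). Between 8447 and 9093 of the calls were kept in the same direction over the alternative fits that tested these 11153 genes, with 7 opposite calls under quantile normalization and none (0) under the others. Limma-voom on the reads called 9185 of 11150 genes. The 2-fold counts moved with the pseudocount: 269 genes at least 2-fold higher and 334 genes at least 2-fold lower at 5, 796 and 1326 at 0.1, and 825 and 1377 with limma-voom, because the pseudocount shrinks the difference of low genes. The lists called with an estimated correlation were 0 higher and 0 lower, and fry called 21 higher, as it does not compare a list with other genes. The direction of p53 targets was reversed by fry (adjusted p = 0.00481) and that of ribosomal proteins by quantile normalization (adjusted p = 0.516), and the cause was not tested. GADD45A stayed between 2.87 and 3.23 on the log2 scale over 16 alternatives. All of these used its DMSO values that are not whole reads, so the range does not bear on that limit. Leaving out 1 library gave 8782 to 8976 calls, the most without DMSO replicate 1, which left 597 genes at least 2-fold higher and 892 genes at least 2-fold lower. The replicate numbers did not pair the samples (correlations of same-numbered deviations -0.0121, -0.00341 and 0.0126, and not every library correlated best with its own number), and with the replicate block 9054 genes were called, and of the named genes H2BC21 had no call (adjusted p = 0.0557 by limma, over a range of 0.00332 to 0.114 in 18 alternatives). Single reads set the limit for genes such as HSPA6, with 1 read per kb worth 0.0252 to 0.0261 FPKM.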

Other observations

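The tests in this part were chosen after the data were seen. Outside the fixed lists, tested genes were grouped by the letters that start their symbol, and the 119 families with at least 10 members were tested with camera (preset correlation 0.01). The aldehyde dehydrogenases were lower, with 13 of 14 fallen, 4 at least 2-fold, 0 risen and 1 not passed (median log2 difference -0.73, adjusted p = 0.0148, and adjusted p = 0.993 with an estimated correlation). ALDH1A1, an enzyme of retinoic acid synthesis, went from 856 to 208 FPKM and ALDH7A1, of lysine breakdown, from 20.7 to 4.79. The zinc finger genes named ZNF were higher, with 182 of 342 risen, 78 fallen and 82 not passed (median 0.19, adjusted p = 0.0148, and adjusted p = 0.993 with an estimated correlation). ZNF503 went from 2.96 to 14.0 FPKM and ZNF473 from 3.94 to 14.6. No other family was called, and these families share no genes with the lists.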
